A study of Rattus norvegicus with 4 samples.

How the data were processed

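Primary cultures of ventricular cardiomyocytes from newborn Wistar rats were grown in a HAM F10 medium that held horse serum and fetal calf serum at 10% each. Supplemented cultures received 60 µM eicosapentaenoic acid (EPA) or docosahexaenoic acid (DHA), and control cultures received neither. The concentration unit is taken from the series' design text, because the unit sign is garbled in the sample descriptions. Medium was renewed every 48 h and cells were harvested at confluence, per the labels. Total RNA was amplified into cRNA, labelled with Cy3 or Cy5 and hybridised to an Agilent rat oligonucleotide array, again per the labels. Each of the 4 arrays carried cRNA of supplemented cells in one channel and of control cells in the other. On array 1 of EPA and of DHA the supplemented cells were in Cy5, and on array 2 in Cy3.

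The authors assessed expression ratios from the labelled cRNA, per the labels, and deposited 1 value per feature and array, read here as a log2 ratio of the channels, for 22575 features. Of these, 2075 were empty on all 4 arrays and 20500 had a value on all 4. The scanner software, background correction, dye normalization, log base and direction of the ratios are not given in the sources used here, and spot intensities were not used here. The array medians as deposited were 0.0024 (EPA array 1), -0.0084 (EPA array 2), -0.0097 (DHA array 1) and -0.0094 (DHA array 2), so the deposited values were already centred.

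The values were read as log2 ratios, a choice made after seeing them. Base 10 is a common output of the scanner software for arrays of this maker, so it stays possible. On EPA array 1, 30 probes shared the value -0.76 within 0.0002, and on DHA array 1, 30 probes shared -0.44. Of the 43 probes at either value 20 were for ribosomal proteins. The 17 probes at both values reached 1.87 on EPA array 2, which would be a 74.5-fold imbalance between the channels in base 10 and is 3.66-fold in base 2. Had the base been 10, every fold given here would be larger.

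The direction was also settled only after seeing the values, and it remains a likely one. The rule fixed before the data were examined turned the values of array 2 if the arrays of each swap correlated clearly below 0, and left them if clearly above. Pearson's r across probes was -0.11 between the EPA arrays and -0.03 between the DHA arrays, which decided neither. The ratios were then read as fatty acid over control on all 4 arrays. The basis is that all 4 sample titles name the supplemented cells, that 38 of the 43 probes with a repeated value, below 0 on the array that repeats it, lay above 0 on both arrays 2, and that 16 of 39 genes of fatty acid oxidation lay above 0 on all 4 arrays. Because those genes helped to choose the reading, their direction is not independent evidence. If the table ran control over fatty acid, every direction given here would turn. If it ran Cy5 over Cy3, the genes called would be others, and those counts are given beside the main ones.

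Probes were named from an old platform annotation, with symbols updated by gene ID through a gene table of the GRCr8 assembly. Of the measured probes 12750 had 1 symbol, 5 had several and were left unnamed, and 7745 were unlisted in the annotation and are unnamed here. The gene ID of 12720 listed probes was found in the gene table, and 35 kept their older symbol. Probes of a gene were averaged, giving 9653 genes, of which 2266 had more than 1 probe. No coordinates are given because no genome build is named.

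Array medians were set to 0. The arrays of a swap were treated as a technical repeat of 1 RNA sample per fatty acid, so neither fatty acid has a replicate check. Whether they hold the same RNA extracts is not given in the sources used here. The swap mean was reported with the half-difference of its 2 arrays as the labelling error. A gene was counted as higher or lower when both arrays of the swap gave at least 1.5-fold in the same direction. The number of genes at 1.5-fold on both arrays in opposite directions, thus following the dye, was taken as the level of dye and array error. A dye bias raises that number but cancels in the swap, so it is no rate of false calls in one direction. For both fatty acids together, limma 3.58.1 in R 4.3.3 (lmFit and eBayes) tested the 2 swap means of each of 20500 probes against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread in that test is the difference between the EPA and DHA samples. Whether both were compared with the same control RNA is not stated, and the control's own spread may be left out. With 4 arrays, the number of arrays limits the precision.

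The 22 gene lists hold 660 genes, of which 527 had a probe, and were fixed before the data were examined, like the tests, the alternatives and the rule for named genes. That rule takes up to 10 genes in each direction per fatty acid that meet the size rule, and jointly the 5 genes in each direction with the smallest p. It also takes the 5 largest EPA to DHA differences in each direction, up to 4 size-rule members per list, and 28 genes chosen for their function, of which 16 had a probe. The percentile of a list's median was taken among 10000 random lists of as many genes, not matched on intensity. It describes these RNA samples and is no p-value.

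The feature numbers were laid out as a grid of 105 rows and 215 columns, inferred from the data: on DHA array 1, Spearman's rho between features was 0.33 at a distance of 1 and 0.35 at a distance of 215. This showed a zone in the first 66 columns of DHA array 1 with many low values. Alternatives added after seeing the data were the Cy5 over Cy3 reading, leaving out those columns, removing a local median of 21 by 21 features, and leaving out the probes with a repeated value. Alternatives fixed beforehand were other centring, scaling, fold thresholds and log base, single arrays, and limma over arrays with and without the replicate number as a block. That number marks the dye orientation per the labels, and the deviations of same-numbered arrays correlated with r = 0.31.

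The procedures were tested on simulated data made from the arrays' own values with 200 of 20500 probes changed. Of these, 50 each were changed 1.5-, 2-, 4- and 8-fold. Each array was shuffled over probes by itself, which removes the correlation between arrays. The 4- and 8-fold changes also ease the adjusted threshold for the 2-fold ones. The shares recovered therefore need not hold for the arrays as measured. The joint limma test recovered 0% of probes changed 1.5-fold, 82% of those changed 2-fold and 100% at 4-fold, with 0 unchanged probes called. The 1.5-fold rule on both EPA arrays recovered 30% at 1.5-fold and 96% at 2-fold with 6 unchanged probes called. On both DHA arrays it recovered 24% and 92% with 2 called. Tables were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.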

Results

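The effect of supplementation with the long-chain polyunsaturated fatty acids EPA and DHA on the transcripts of neonatal rat cardiomyocytes was examined on 4 arrays. Ventricular cells of newborn rats in primary culture contain beating cardiomyocytes together with fibroblasts and other cells of the heart wall. EPA and DHA, the main fatty acids of fish oil, were each given at 60 µM, and each supplemented culture was compared directly with an unsupplemented control on 2 arrays with exchanged dyes. The labels do not say whether the 2 arrays of a fatty acid hold the same RNA extracts or separate ones. They are treated here as 1 RNA sample against 1 control RNA, without a replicate check. If the extracts were separate, the difference between the arrays of a swap would also hold that between extracts. Values are log2 ratios given as mean ± half-difference of the 2 arrays of a swap, read as fatty acid over control. That direction is likely and not stated, so all directions would turn together if the table ran the other way. The log base is not stated either, and all folds would be larger in base 10.

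The arrays spanned a narrow range. The interquartile range of all 20500 probes was 0.26 on EPA array 1, 0.22 on EPA array 2, 0.26 on DHA array 1 and 0.19 on DHA array 2. DHA array 1 differed from the others by a long negative tail, with its first percentile at -2.11 against -0.62, -0.40 and -0.36 on EPA array 1, EPA array 2 and DHA array 2. Of its 1090 values under -1, 1082 (99.3%) lay in the first 66 of the 215 inferred grid columns, which hold 30.6% of the features. The other arrays were shifted there too, without such a tail: the medians in those columns and in the others were 0.11 and -0.033 on EPA array 1, -0.038 and 0.0049 on EPA array 2, and -0.085 and 0.018 on DHA array 2, against -0.13 and 0.017 on DHA array 1. Genes named below with a probe in those columns are marked, because their EPA and DHA means and the difference between them can rest on these shifts.

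**Figure D1:**
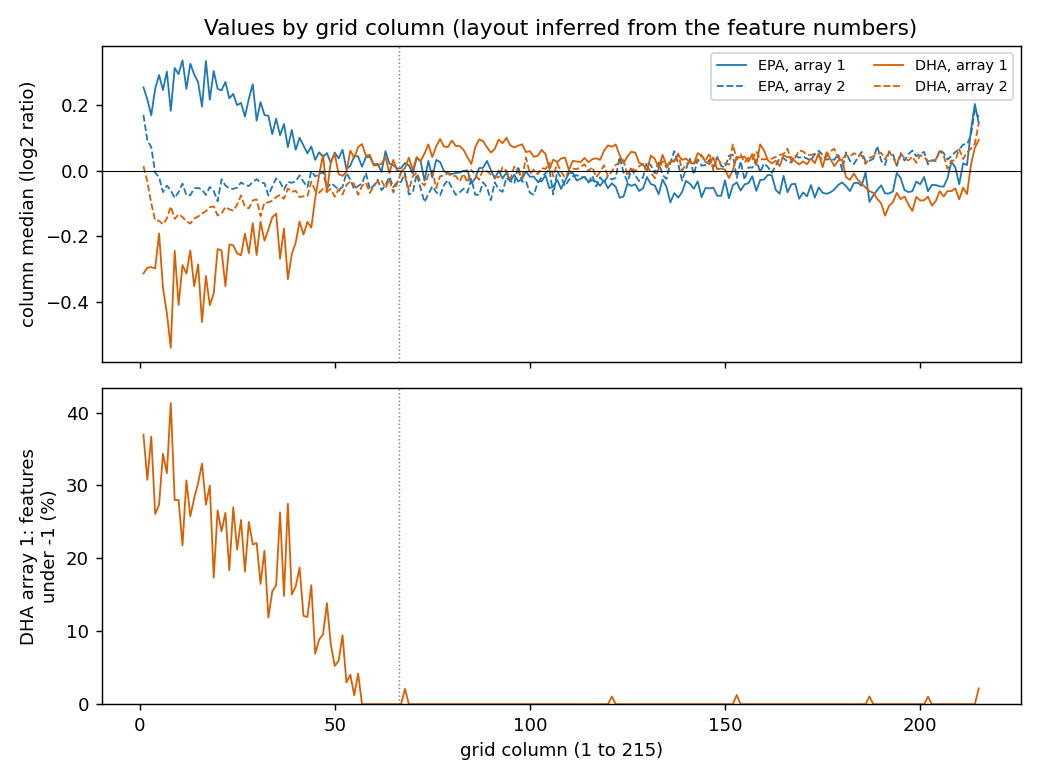
Median log2 ratio of each grid column on the 4 arrays (upper panel) and percent of features under -1 on DHA array 1 (lower panel), against the grid column inferred from the feature numbers. The dotted line closes column 66; up to it 17.2% of the features of DHA array 1 lay under -1, and beyond it 0.0563%.

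The first comparison asked which transcripts differed between EPA-supplemented and control cells. Of 9653 genes, 3 were at least 1.5-fold higher on both EPA arrays and 0 were lower. Cpt1b, the muscle form of the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, was higher by 0.91 ± 0.02, or 1.87-fold. Dhrs3, a retinal reductase, was higher by 0.71 ± 0.02 (1.64-fold), and Hilpda, a lipid droplet protein, by 0.67 ± 0.08 (1.59-fold). Centring the arrays without the first 66 columns ended the call of Hilpda: its probe lies outside them, and the new centre moved EPA array 2 from 0.59 to 0.577, under the threshold of 0.585, with a mean of 0.68 ± 0.10 (1.60-fold). Other genes of lipid handling passed the threshold on 1 array of the swap: Cpt1a, the liver form of the same enzyme, stood at 0.72 ± 0.36, Ech1, an auxiliary enzyme of fatty acid oxidation, at 0.77 ± 0.26, and Plin2, a coat protein of lipid droplets, at 0.49 ± 0.22. Ucp3, a mitochondrial carrier, was at 0.37 ± 0.18 and reached the threshold on neither array.

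At the lower threshold of 1.3-fold, 17 genes were higher and 8 lower with EPA, of which 10 and 6 have no probe in the first 66 columns. More genes followed the dye than the treatment: 27 genes at 1.5-fold and 72 at 1.3-fold on both EPA arrays went in opposite directions between the arrays. The count of 3 lies below this count of 27. All 27 lay below 0 on EPA array 1 and above 0 on EPA array 2, as a dye bias would place them. Such a bias cancels in the swap, so 27 gives no rate of false calls in one direction. Counted by probe, 7 were called, against 6 unchanged probes in the simulated data with each array shuffled. Under the Cy5 over Cy3 reading of the table those 27 genes would be the ones called, all lower with EPA. Scaling the arrays to equal spread gave 4 higher and 1 lower, and quantile normalization 4 higher and 19 lower.

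Genes of the functional groups chosen beforehand stayed mostly near 0 with EPA. Of the genes in this paragraph, Fabp3, Fasn, Insig1 and Atp2a2 and 1 of the 2 probes each of Nppb, Hmox1 and Ptgs2 lie in the first 66 columns. Pdk4, a kinase that restrains pyruvate oxidation, was at -0.02 ± 0.10, and Fabp3, the fatty acid binding protein of heart, at 0.32 ± 0.07. Among genes of fatty acid synthesis and desaturation, Fasn was at -0.06 ± 0.05, Fads1 at -0.26 ± 0.01 and Fads2 at -0.0059 ± 0.17, and Insig1, a sterol sensor, was at -0.05 ± 0.0049. The natriuretic peptide genes Nppa and Nppb, markers of cardiac stress, were at -0.09 ± 0.13 and -0.27 ± 0.25. The myosin heavy chain gene Myh6 was at 0.11 ± 0.06 and the calcium pump gene Atp2a2 at 0.06 ± 0.11. Col3a1, a collagen, was at -0.08 ± 0.07, Hmox1, heme oxygenase, at 0.12 ± 0.18 and Ptgs2, a prostaglandin synthase, at -0.09 ± 0.01. None of these genes met the size rule.

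The second comparison asked the same of DHA. Here 4 genes were at least 1.5-fold higher on both arrays and 4 lower. Cpt1b was higher by 1.14 ± 0.16 (2.20-fold) and Hilpda by 0.74 ± 0.04 (1.67-fold). Star, which carries cholesterol into mitochondria for steroid synthesis, was higher by 0.84 ± 0.14 (1.79-fold), and Asip, the agouti signalling protein, by 0.71 ± 0.12 (1.64-fold). Lower were Mmp12, the macrophage elastase, at -0.84 ± 0.21 and Ceacam4, a member of the carcinoembryonic antigen family, at -0.82 ± 0.07. Grem1, an extracellular antagonist of bone morphogenetic proteins, was lower at -0.69 ± 0.03, as was Gpc3, a cell surface proteoglycan, at -0.69 ± 0.10. None of these 8 genes has a probe in the first 66 columns. Of the 2 probes of Mmp12, 1 alone met the rule. The call of Asip ended when the arrays were centred without those columns, DHA array 2 moving from 0.59 to 0.57 and the mean to 0.68 ± 0.12 (1.61-fold).

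Ech1 was at 0.90 ± 0.38 with DHA, Cpt1a at 0.66 ± 0.25, Plin2 at 0.50 ± 0.13, Dhrs3 at 0.47 ± 0.01 and Ucp3 at 0.44 ± 0.07. Pdk4 was at 0.11 ± 0.0036, Fads1 at -0.11 ± 0.22, Fads2 at -0.00095 ± 0.0093 and Nppa at -0.13 ± 0.17. Myh6 was at 0.14 ± 0.01 and Col3a1 at -0.10 ± 0.06. Several other genes of this group have a probe in the first 66 columns. Of these, Atp2a2 was at -0.71 ± 0.76, Fabp3 at -0.21 ± 0.36, Fasn at -0.08 ± 0.02 and Insig1 at -0.10 ± 0.12. Nppb was at -0.11 ± 0.16, Hmox1 at 0.10 ± 0.23 and Ptgs2 at -0.31 ± 0.26, each with 1 of 2 probes in those columns.

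At 1.3-fold 14 genes were higher and 23 lower with DHA, but 12 of the lower and 1 of the higher have a probe in the first 66 columns, leaving 13 higher and 11 lower outside them. On both DHA arrays 5 genes at 1.5-fold and 69 at 1.3-fold followed the dye. Those 5 genes would be the ones called under the Cy5 over Cy3 reading, all lower with DHA. Quantile normalization gave 5 higher and 10 lower genes at 1.5-fold. Removing a local median gave 2 higher, Cpt1b and Hilpda, and 3 lower, Ceacam4, Grem1 and Mmp12. The calls of Star, Asip and Gpc3 ended because 1 array of each came under the threshold, with means of 0.74 ± 0.22 (1.67-fold), 0.68 ± 0.10 (1.60-fold) and -0.67 ± 0.16 (0.629-fold).

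**Figure D2:**
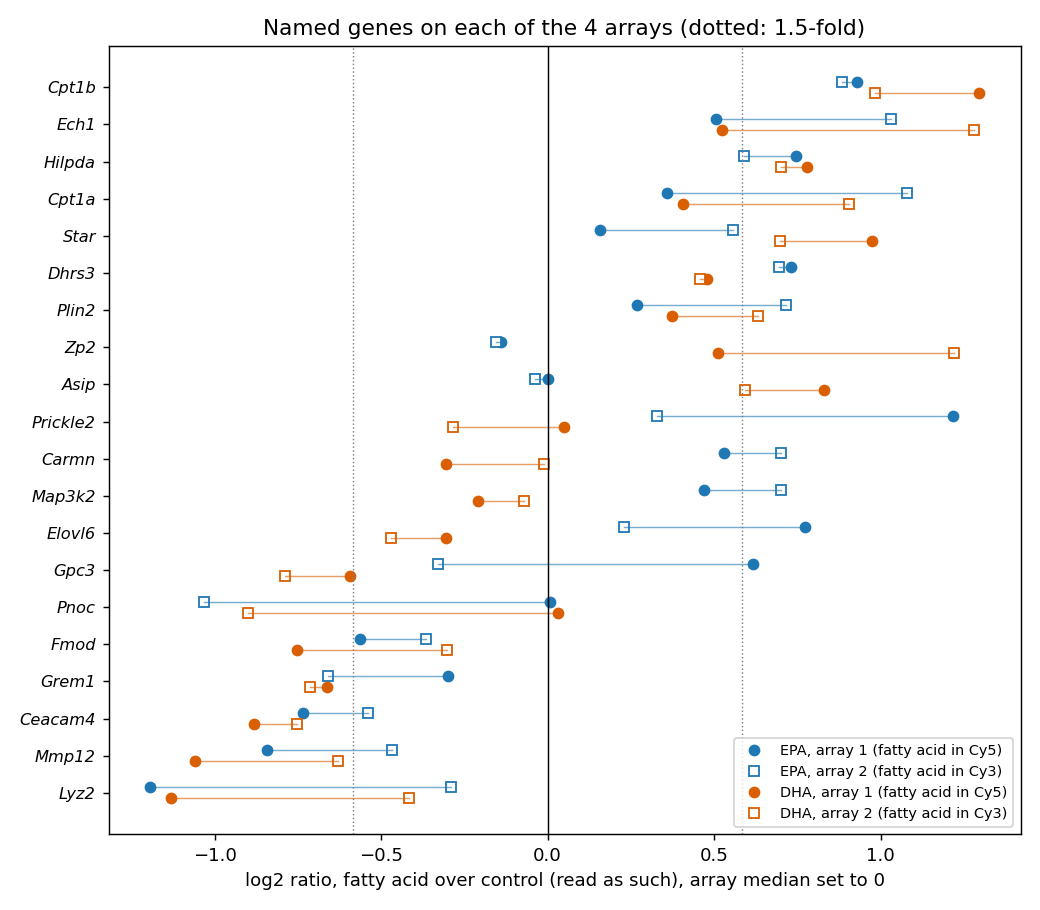
Log2 ratio of each gene named by size, by the joint ranking or by its EPA to DHA difference on each of the 4 arrays, with EPA in blue and DHA in orange, filled circles for array 1 and open squares for array 2, and a line joining the arrays of a swap. Cpt1b lay at 0.88 or above on each of the 4 arrays and Ceacam4 between -0.88 and -0.54, whereas Pnoc lay near 0 on both arrays 1 and at -1.03 and -0.90 on arrays 2.

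The third comparison asked which transcripts differed from control in both supplemented samples. By limma on the 2 swap means, 0 of 20500 probes passed an adjusted p of 0.05, the smallest adjusted p being 0.891. Unadjusted p lay under 0.05 for 909 probes, where chance alone gives 1025. Among named genes, those above control with the smallest p were Ech1, with a joint mean of 0.84 ± 0.07 (SE), Cpt1b at 1.02 ± 0.09, Hilpda at 0.70 ± 0.06, Cpt1a at 0.69 ± 0.06 and 1 of the 2 probes of Plin2 at 0.62 ± 0.06. Those below were 1 of the 2 probes of Lyz2, the lysozyme of macrophages, at -0.89 ± 0.07, Mmp12 (1 of 2 probes) at -0.69 ± 0.07, Ceacam4 at -0.73 ± 0.08, Fmod, a proteoglycan of the matrix, at -0.50 ± 0.06, and Pnoc, a neuropeptide precursor, at -0.47 ± 0.06. Each of these had an adjusted p of 0.891. The SE rests on the EPA to DHA difference of the swap means and leaves out the difference between the arrays of a swap. The half-differences with EPA and DHA were 0.26 and 0.38 for Ech1 and 0.52 and 0.47 for Pnoc. Pnoc lay at 0.01 and 0.03 on arrays 1 of EPA and DHA, so it was not below control there. The 2 probes of Lyz2 differed on EPA array 1, at -1.66 and -0.73, and those of Plin2 at 0.56 and -0.02.

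Without the first 66 columns, 2 of 14222 probes passed, at adjusted p of 0.017 and 0.0247 by limma. Both are unlisted in the annotation, and their ratios were 1.46 and 1.12 when centred without those columns. Unadjusted p then lay under 0.05 for 1749 probes, where chance alone gives 711, an excess to which a shared control could add. How many probes a shared control alone would give was not computed. With limma over the 4 arrays, 0 probes passed with or without the replicate number as a block.

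Without a test, the arrays were also compared by size alone. At 1.3-fold, 8 probes were higher and 5 lower on all 4 arrays, together 13, against a mean of 1.51 and at most 5 when arrays 1 were shuffled jointly against arrays 2 in 100 rounds. That shuffle keeps the correlation within a dye orientation and removes what a shared control adds across orientations, so it gives too low a reference if the control was shared. At the same threshold 56 probes went one way on arrays 1 and the other way on arrays 2, or 26 without the probes that share a repeated value. At 1.5-fold on all 4 arrays 3 probes were higher and 0 lower.

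Read as fatty acid over control, members of the fatty acid oxidation list lay above control on all 4 arrays more often than those of the other lists. Of its 39 measured genes, 1 (Cpt1b) was higher and 0 lower by the size rule in each comparison, and 16 (41.0%) lay above 0 on all 4 arrays, against 676 of all 9653 genes. The highest share among the other lists was 17.1%. Read as Cy5 over Cy3, 3 of the 39 genes lay above 0 on all 4 arrays, and 14 of 38 of oxidative phosphorylation. The list's median was 0.11 with EPA and 0.16 with DHA, in each case at percentile 100 of random lists. This place rests on the reading. As Cy5 over Cy3 the list's medians were -0.058 with EPA (percentile 2.25) and -0.015 with DHA (percentile 57), and over the 4 arrays -0.047 (percentile 11.4), below fatty acid synthesis at 0.054 (98.4) and oxidative phosphorylation at 0.037 (98.9). Besides Cpt1b, Ech1, Cpt1a and Plin2, examples chosen after their values were seen are Decr1, an accessory oxidation enzyme, at 0.31 with EPA and 0.55 with DHA, and Acadvl, the very long-chain acyl-CoA dehydrogenase, at 0.24 and 0.38. Ppara and Ppargc1a, regulators of this pathway in the same list, were at -0.06 and -0.04 over the 4 arrays, Ppargc1a with its probe in the first 66 columns. These genes took part in choosing the direction, so the side on which they lie is not independent evidence.

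Lists of other cell types and of the contractile apparatus held no gene that met the size rule in either comparison. The sarcomere and cardiomyocyte list had medians of 0.016 with EPA and 0.0044 with DHA, and the calcium handling list 0.0079 and -0.0023. The sarcomere list changed sign with the dye, at -0.10 and 0.034 on EPA arrays 1 and 2 and -0.064 and 0.041 on DHA arrays 1 and 2. Read as Cy5 over Cy3 it stood at -0.063 with EPA (percentile 4.51) and -0.059 with DHA (percentile 14.05). For fibroblast markers and extracellular matrix the median was 0.12 with EPA (percentile 100) and -0.078 with DHA (percentile 0.4). As Cy5 over Cy3 the medians were -0.044 (percentile 7.89) and -0.22 (percentile 0), so EPA stayed above DHA while its side of 0 turned. As deposited, the medians on arrays 1 were 0.031 with EPA and -0.30 with DHA, and on arrays 2 they were 0.081 and 0.080. The difference between EPA and DHA in this list thus came from arrays 1 and was absent on arrays 2. In the fatty acid over control reading the DHA median without the first 66 columns was -0.032 (percentile 3.7). The sarcomere list without those columns had -0.017 with either fatty acid. Col1a2, Fn1 and Bgn of the fibroblast list have probes with a repeated value on arrays 1. The smooth muscle list changed sign with the dye, at -0.13 and 0.24 on EPA arrays 1 and 2 and -0.40 and 0.077 on DHA arrays 1 and 2. Its medians of 0.12 with EPA (percentile 98.3) and -0.035 with DHA thus balance opposite values (-0.23 and -0.27 as Cy5 over Cy3). The DHA median turned to 0.015 under quantile normalization and was -0.062 without the first 66 columns. The endothelial list had medians of 0.034 and 0.037, and the macrophage and leukocyte list -0.047 and -0.049, or -0.035 and -0.016 without those columns. The red cell list stood at -0.025 and 0.049.

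Among metabolic lists, cholesterol synthesis and LDL uptake had a median of -0.014 with EPA, at percentile 33.4, and -0.11 with DHA, at percentile 0.42. Without the first 66 columns the medians over 14 genes were 0.024 with EPA and -0.12 with DHA, the latter at percentile 0. Read as Cy5 over Cy3 the list stood at -0.0079 with EPA and 0.018 with DHA (percentile 86.8). Sc5d, a sterol desaturase outside those columns and chosen after its values were seen, was at -0.14 with EPA and -0.22 with DHA. Fatty acid synthesis and desaturation had medians of 0.028 and 0.018. Glycolysis and glucose uptake had medians of 0.097 at percentile 99.9 with EPA and 0.042 at percentile 96 with DHA, or 0.012 (percentile 68.4) and 0.022 (percentile 92) as Cy5 over Cy3. Oxidative phosphorylation and the citrate cycle stood at 0.0023 and 0.0052, or 0.013 and 0.048 (percentile 99.7) without the first 66 columns. None of these lists had a member that met the size rule.

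Stress and growth lists likewise had 0 genes past the size rule. Inflammatory mediators had medians of -0.058 with EPA (percentile 1.55) and -0.10 with DHA (percentile 0.13), and 7 of 28 genes lay below 0 on all 4 arrays. These ranks rest on the reading: as Cy5 over Cy3 the medians were 0.010 (percentile 67) and -0.010 (percentile 62.8), with 5 genes above 0 and 6 below on all 4 arrays. Leaving out its 1 gene with a repeated value, the DHA median was -0.057 (percentile 3.39). The cell cycle list had medians of -0.050 and -0.057, at percentiles 1.64 and 1.67, with 10 of 37 genes below 0 on all 4 arrays, or 0.0015 (percentile 57.2) and -0.085 (percentile 1.46) with 3 genes below 0 as Cy5 over Cy3. Without the first 66 columns its DHA median was 0.00064, and the inflammatory list's -0.049 (percentile 0.68). Antioxidant genes had medians of -0.039 with EPA and 0.082 with DHA (percentile 100), hypertrophy and fetal cardiac genes 0.00099 and -0.089 (percentile 0.51). With a local median removed the antioxidant EPA median was 0.0013 (percentile 60.75), so its side of 0 is not settled. Apoptosis genes had medians of -0.073 (percentile 0.5) and 0.0043, and heat shock proteins -0.031 and -0.10. Removing a local median moved the EPA median of the apoptosis genes to -0.036 (percentile 10.46). Endoplasmic reticulum stress genes had 0.054 and -0.044. Eicosanoid synthesis genes had 0.020 and -0.038, and interferon response genes -0.0041 and -0.081. On DHA arrays 1 and 2 the medians were -0.18 and 0.00022 for inflammatory mediators and -0.17 and -0.017 for hypertrophy. They were -0.22 and -0.0036 for heat shock proteins, -0.11 and 0.041 for endoplasmic reticulum stress and -0.16 and 0.074 for the interferon response. The low DHA medians of these lists thus rest on DHA array 1. They do not all rest on the first 66 columns. Without those, the DHA median was -0.11 (percentile 0.1) for heat shock proteins and -0.049 (percentile 1.69) for endoplasmic reticulum stress. The interferon list also changed sign between EPA arrays 1 and 2, at -0.11 and 0.047. The DHA medians outside the first 66 columns were -0.039 (percentile 3.14) for hypertrophy, -0.00094 for eicosanoid synthesis, 0.028 for apoptosis, 0.069 for antioxidant genes and -0.11 (percentile 0.06) for the interferon response. Under the Cy5 over Cy3 reading the antioxidant list stood at -0.014 with DHA (percentile 58.2), apoptosis at -0.0014 with EPA (percentile 53.9), hypertrophy at -0.12 with DHA (percentile 0.49) and the interferon response at -0.14 with DHA (percentile 1.13). Ribosomal protein genes followed the dye, with medians of -0.54 and 0.47 on EPA arrays 1 and 2 and of -0.23 and 0.36 on DHA arrays 1 and 2, so their swap means of 0.0081 and 0.17 are differences of larger opposite values. Of their 29 genes 12 had a probe with a repeated value. Without those probes 21 genes remained, with medians of -0.096 with EPA (percentile 0.07) and 0.043 with DHA (percentile 95.2), and under quantile normalization the EPA median was -0.073 (percentile 1.34), so neither the side nor the rank of this list is settled.

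**Figure D3:**
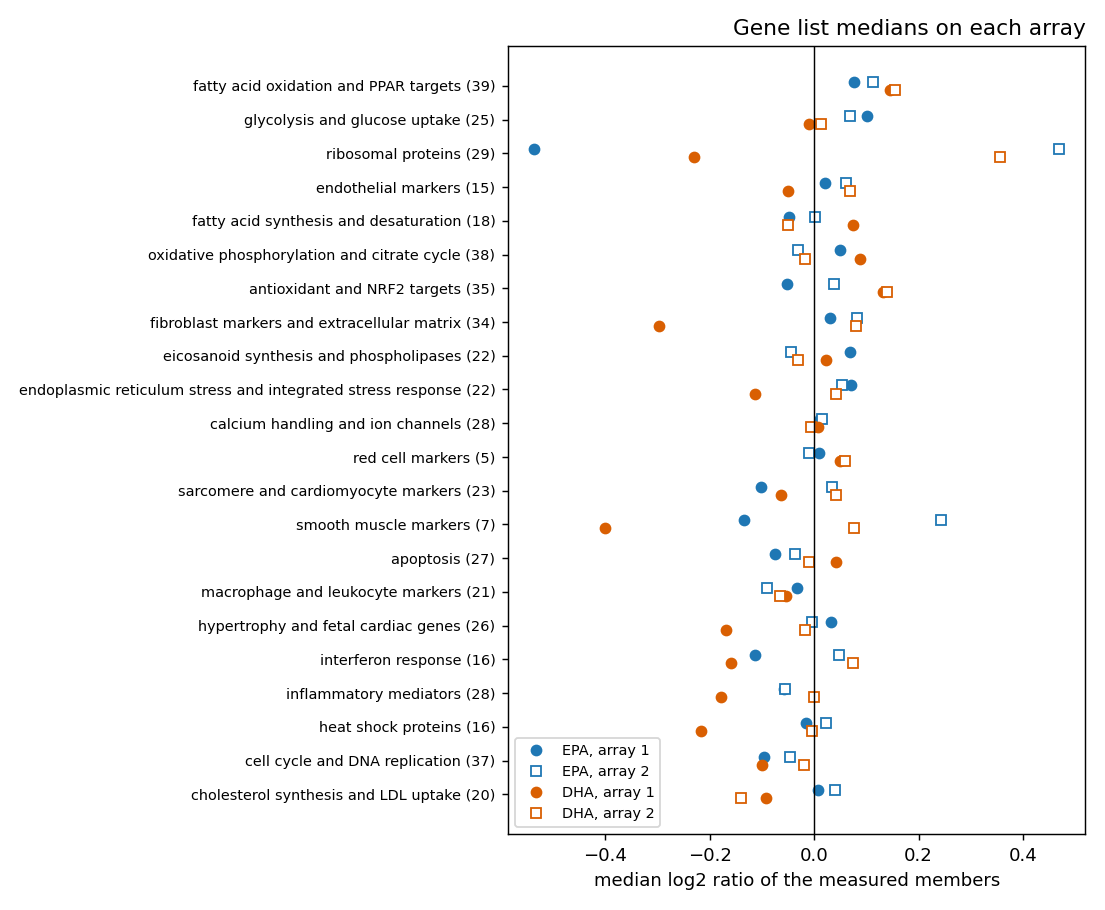
Median log2 ratio of the measured members of each gene list on each array, with EPA in blue and DHA in orange, filled circles for array 1 and open squares for array 2, and the number of measured genes in brackets. The fatty acid oxidation list lay at 0.08, 0.11, 0.15 and 0.16 on EPA arrays 1 and 2 and DHA arrays 1 and 2, while the ribosomal protein list changed sign with the dye. The smooth muscle, interferon response, sarcomere, oxidative phosphorylation and eicosanoid synthesis lists also changed sign with the dye.

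The last comparison set EPA against DHA, a fatty acid with a longer chain and an additional double bond, at the same concentration of 60 µM. The difference was at least 1.5-fold in the same direction within both dye orientations for 6 genes. With EPA 4 were higher: Prickle2, a planar cell polarity protein, by 0.89 ± 0.28, Elovl6, a fatty acid elongase, by 0.89 ± 0.19, Carmn, a noncoding RNA of cardiac and smooth muscle, by 0.77 ± 0.06, and Map3k2, a kinase, by 0.73 ± 0.05. Lower with EPA were Zp2, an egg coat protein, at -1.02 ± 0.36, and Asip, at -0.73 ± 0.10. All probes of Elovl6, Carmn and Map3k2 lie in the first 66 columns, where the opposite shifts of EPA array 1 and DHA array 1 raise the difference. Neither of the 2 probes of Map3k2 met the rule alone, with 0.57 and 1.49 in the 2 orientations for one and 0.79 and 0.06 for the other. After a local median was removed the calls of these 3 genes and of Zp2 ended, because their difference between arrays 1 came under the threshold. The differences were then 0.59 ± 0.03 (1.51-fold) for Elovl6, 0.58 ± 0.07 (1.49-fold) for Carmn, 0.41 ± 0.28 (1.33-fold) for Map3k2 and -0.92 ± 0.37 (0.527-fold) for Zp2. As an error level, 3 genes differed by 1.5-fold in opposite directions in the orientations. Scaling the arrays to equal spread gave 9 higher and 2 lower, quantile normalization 26 and 11, and the Cy5 over Cy3 reading 3 and 0.

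Intervals of 95% for EPA minus DHA were taken by limma over the 4 arrays without the replicate block, which leaves the dye orientation in the error, and with the block. For the genes that stood highest in both comparisons they included 0. The difference was -0.23 for Cpt1b (-0.66 to 0.19, with the block -0.61 to 0.15), -0.07 for Hilpda (-0.42 to 0.28, with the block -0.38 to 0.23), 0.07 for Cpt1a (-0.80 to 0.93, with the block -0.29 to 0.42) and -0.13 for Ech1 (-1.04 to 0.77, with the block -0.49 to 0.23). For Star, called with DHA alone, it was -0.48 (-1.03 to 0.06, with the block -1.15 to 0.18), and for Dhrs3, called with EPA alone, 0.24 (-0.07 to 0.56, with the block -0.05 to 0.54). Gpc3, also called with DHA alone, differed by 0.84 (-0.11 to 1.78), and its interval left 0 out with the block (0.11 to 1.56). For Mmp12, Ceacam4 and Grem1, the other lower genes of DHA, both intervals included 0.

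Of the genes called different between EPA and DHA, whose intervals are taken after choosing them for size, 5 had intervals without 0 in both fits. Without the block these were -1.11 to -0.35 for Asip, 0.33 to 1.22 for Carmn, 0.33 to 1.12 for Map3k2 and -1.74 to -0.29 for Zp2, and for Elovl6 the lower end was 0.28. For Prickle2 it was -0.04 to 1.82, and 0.32 to 1.47 with the block. None of these passed adjustment across genes by limma, the adjusted p being 0.778 with the block and higher without it. These intervals cover the spread between arrays and leave out that between cultures. By limma over the 4 arrays 0 probes differed between EPA and DHA, with 218 at an unadjusted p under 0.05, or 359 with the replicate block. Both lie under the 1025 that chance alone gives.

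Across genes, which are not independent replicates, the EPA and DHA swap means correlated with r = 0.11 (Spearman 0.11) and a covariance of 0.0037. Unchanged samples against 1 shared control gave r = 0.36 and a covariance of 0.010 in 100 simulations. Without the first 66 columns the observed r was 0.37, and with a local median removed it was 0.34. The r of 0.11 thus also holds the opposite shifts of EPA array 1 and DHA array 1 in those columns. No simulated value is at hand for either setting, so neither 0.37 nor 0.34 is to be set against 0.36. Both swap means reached 1.5-fold upwards for 5 genes and downwards for 3, where the simulated shared control gave means of 0.08 and 3.58. The 3 lower genes, Lyz2, Mmp12 and Ceacam4, have no probe in the first 66 columns. Of the 463 genes 1.5-fold lower by the DHA swap mean, 456 have one there. No simulated count is at hand without those columns, so 3 is not to be set against 3.58. Of the genes called by the size rule, 2 (Cpt1b and Hilpda) were shared, or 1 (Cpt1b) when centred without the first 66 columns. What a shared control alone would give for this overlap was not computed.

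**Figure D4:**
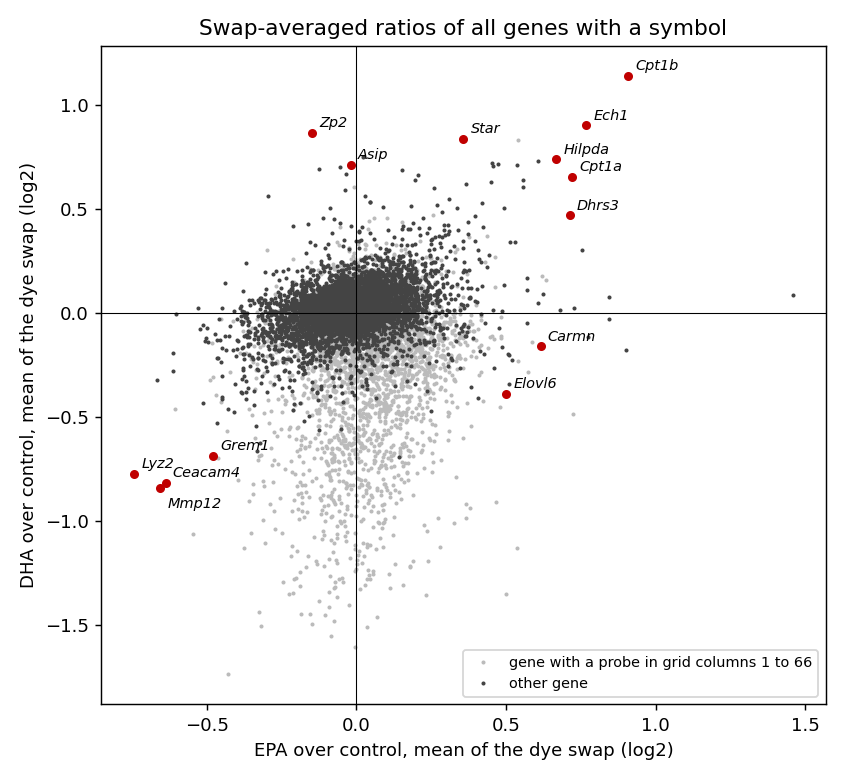
Swap-averaged log2 ratio of EPA over control (horizontal axis) and DHA over control (vertical axis) for each gene with a symbol, grey where a probe lies in grid columns 1 to 66, black otherwise, and red for 14 labelled genes. Cpt1b lay at 0.91 and 1.14, and the grey genes form the downward spread on the DHA axis.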

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

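All tests of explanations in this part were chosen after the results were seen. Of the genes named above, 4 lay on one side of 0 on both EPA arrays and on the other side on both DHA arrays, and the differences were not tested across cultures. EPA minus DHA was 0.77 for Carmn, 0.89 for Elovl6, 0.73 for Map3k2 and -1.02 for Zp2. Only Zp2 has its probe outside the first 66 grid columns, in which EPA array 1 is shifted upwards and both DHA arrays downwards.

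Among 7745 probes that the annotation does not list, 5 were at least 1.3-fold from control in the same direction on all 4 arrays. Probe 12385 averaged 1.47 over the 4 arrays and probe 21876 averaged 1.13. Both exceeded the mean of Cpt1b, 1.02. Probe 11300 averaged 0.68. Probe 1539, which lies in the first 66 columns, averaged -0.86 and probe 13430 averaged -0.52. Their genes are not named here.

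The shared side of the fatty acid oxidation genes was weighed against 3 explanations. If the values ran by dye, a dye bias of these genes could give the shared side, and this cannot be told. The arrays of a swap should then be the most opposed. Pearson's r of array 1 with array 2 of the same fatty acid minus that with array 2 of the other was 0.22 for EPA and 0.04 for DHA, which speaks against it, but -0.10 for DHA once a local median was removed. Probe position is argued against, since 41.0% of the list lay above 0 on all 4 arrays before a local median was removed and 43.6% after, where the highest of 10000 random lists reached 25.6%. This holds for the signs as deposited, and as Cy5 over Cy3 only 3 of 39 genes lay above 0 throughout. A larger share of cardiomyocytes would raise their markers at least as much, yet these had a median of -0.015, with a bootstrap interval of -0.034 to 0.042, against 0.13 for the list. The marker medians changed sign with the dye, at -0.10 and 0.034 on EPA arrays 1 and 2 and -0.064 and 0.041 on DHA arrays 1 and 2. They therefore speak against a larger share only as far as the swap cancels the dye, and intensities were not used. A difference between the single cultures unrelated to the fatty acids stays open too, beside a response to supplementation, which is a hypothesis.

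Lyz2, Mmp12 and Ceacam4 lay below 0 on all 4 arrays, and Lyz2 and Mmp12 are known from macrophages. Probe position is argued against, because after a local median was removed the highest of their 3 means was -0.72. Fewer macrophages in the supplemented cultures may be involved and this cannot be told apart from lower expression per cell. The other 20 macrophage and leukocyte markers had a median of -0.033 (bootstrap interval -0.12 to 0.010), far from the -0.75 of the 3 genes, but without intensities a marker near 0 may be at background. Of the 21 measured markers including Lyz2, 5 (23.8%) lay below 0 on all 4 arrays and 0 above, while 7.6% of all genes lay below. Besides Lyz2 these were Cd14 at -0.18, C1qb at -0.18, Fcgr2b at -0.29 and Tyrobp, with a probe in the first 66 columns, at -0.61. Without those columns 4 of 13 lay below and 0 above. As Cy5 over Cy3, 2 of 21 lay above and 2 below. Cd68 averaged 0.04.

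The long negative tail of DHA array 1 was also weighed. A local fault of the array is what the position points to, with 99.3% of the values under -1 in the first 66 columns. A lowering of these genes by DHA is argued against by DHA array 2, itself shifted downwards in those columns, where the same 1090 probes had a median of -0.0065 and quartiles of -0.11 and 0.11. What kind of fault it was is not known.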

How the results depend on the processing

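The EPA count of 3 genes and the DHA count of 8 stayed within 1.5 times when arrays were not centred (2 and 7), when probes with a repeated value were left out (3 and 8) and without the first 66 columns (2 and 7), the last 2 chosen after seeing the data. Without those columns the calls of Hilpda with EPA and of Asip with DHA ended. The causes of the moves below were not tested, except where a setting's own construction gives more or fewer genes. At 2-fold on both arrays, or in both orientations, the EPA, DHA and EPA against DHA counts were 0, and at 1.3-fold 25, 37 and 39. Asking 1.5-fold of the swap mean alone gave 29 with EPA and 490 with DHA (27 higher and 463 lower, 456 of the lower with a probe in the first 66 columns, where DHA array 1 has its negative tail), and counting each probe by itself 7 and 13. Scaling to equal spread gave 5 with EPA and 11 for EPA against DHA. Quantile normalization gave 23, 15 and 37. Read as base 10 the counts were 477, 479 and 579. Read as Cy5 over Cy3 they were 27, 5 and 3, and the DHA means of Gpc3 and Grem1 turned to 0.10 and 0.026. Removing a local median left 5 with DHA, and for EPA against DHA ended the calls of Carmn, Elovl6, Map3k2 and Zp2 while 2 others began.

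Single arrays, where the dye is not cancelled, gave 83 to 307 genes with EPA, 83 to 968 with DHA and 46 to 1318 for EPA against DHA. The joint limma test on arrays 2 alone called 1680 probes and on arrays 1 alone 0. On arrays 2 alone the dye that both fatty acids share cannot be parted from a shared effect. Arrays 1 hold the other dye orientation, and the calls of arrays 2 were not repeated there. As deposited, r was 0.65 between EPA array 2 and DHA array 2. With these, EPA array 1 correlated at -0.11 and -0.32, so what arrays 2 share mostly did not carry over to EPA array 1. The joint count was 2 without the first 66 columns and 3 by the 1.5-fold rule on all 4 arrays, and it stayed at 0 under the other settings run. Limma over arrays with the swap arrays as replicates gave 0 for EPA, DHA and their difference, with the replicate block and without it. Its counts at an unadjusted p under 0.05 were 590 for EPA and 439 for DHA without the block, and 1168 and 885 with it. Chance alone gives 1025 of 20500 probes, which only the count of 1168 exceeded.

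Of the values of named genes under the alternatives, 518 moved by less than the spread of the swap, 146 by more, and 2 reversed. Of list medians 291 moved by less and 105 by more. Intensities were not used here, so no limit from signal over background can be given.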

Other observations

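Some genes outside the rule for named genes, chosen after their values were seen, kept one side of 0 on all 4 arrays. In the antioxidant list these were Nqo1, a quinone reductase, with a mean of 0.43, Keap1, which restrains the antioxidant regulator Nfe2l2, with 0.37, Mt2A, a metallothionein, with 0.30, and Osgin1 with 0.28. Slc7a11, a cystine carrier in the same list, was at -0.26 and Sod3, the extracellular superoxide dismutase, at -0.22, so the list had members on both sides. The probe of Keap1 lies near the array's edge, in grid column 213, whose own medians were 0.12, 0.11, 0.018 and 0.067 on EPA arrays 1 and 2 and DHA arrays 1 and 2. Nrep averaged 0.67.

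Below 0 on all 4 arrays were the atrial light chain gene Myl7, at -0.38, and Sln, sarcolipin, an inhibitor of the calcium pump, at -0.36. Replication genes Mcm5 and Mcm6 averaged -0.39 and -0.24, Mcm6 with 1 of 2 probes in the first 66 columns. Pcna and Mcm4 had lower means of -1.08 and -0.91, but both have their probe in the first 66 columns and stood at -0.14 and -0.17 on DHA array 2. Among inflammatory mediators, Il6 averaged -0.29 and Cxcl1 -0.30. None of these values passed a test. Of all 9653 genes, 676 lay above 0 on all 4 arrays and 733 below.

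Correlations between arrays were uneven. Across probes Pearson's r was 0.65 between EPA array 2 and DHA array 2, 0.06 between EPA array 1 and DHA array 1, and -0.32 between EPA array 1 and DHA array 2. Without the first 66 columns the arrays 1 correlated with r = 0.38.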
